A study of Mus musculus with 6 samples.

How the data were processed

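Gene expression was measured by RNA sequencing in endosteal mesenchymal stromal cells of C57BL/6J mice, in 3 libraries labelled Bap1 WT (Bap1fl/fl) and 3 labelled Bap1 cKO (Prx1-cre;Bap1fl/fl). Per the labels, RNA was taken up in TRIzol, made into stranded polyA libraries and read as 151 bp pairs. The submitters' processing notes name cutadapt 2.8, STAR 2.7.1a, RSEM 1.3.1 and the genome build GRCm38, and give no annotation version. The authors deposited the values as RPKM, that is per kilobase of gene and scaled to the mapped reads of each library, with 2 decimals for 55471 Ensembl gene identifiers in 6 columns. Column totals ran from 678450.39 to 700082.31, and no library was pooled.

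Symbols and coordinates came from GENCODE M21, which held 55144 of the identifiers and lacked 327, so coordinates are those of that annotation and not necessarily of the one used for the values. A symbol stood on more than 1 identifier in 106 cases, and 32449 genes were 0 in all 6 libraries. No gene of 52 ribosomal and oxidative phosphorylation genes was at 0 in any library. Read counts are not used here. The depth of each library was estimated from the steps between low values of genes with transcripts of 800 to 3500 bp, less 150 bp, and 78.3 to 90.6% of these values lay within 0.2 of a whole number of fragments, where chance gives 40%. A floor of 3 fragments per effective kilobase was then 0.136 to 0.231 RPKM.

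Differences were tested with limma 3.58.1 in R 4.3.3, 2-sided, on log2(RPKM + 1) with a moderated variance that follows the mean, for genes with a mean of at least 1 RPKM over the 6 libraries. Genotype was the only term. The Benjamini-Hochberg adjusted p had to lie under 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, for lists with at least 5 tested members, adjusted over 30 lists. The same test with an estimated correlation and the rotation test fry stand beside it. Of the 30 lists, 2 were higher and 12 lower with the preset correlation and 0 passed with an estimated one, while fry gave 20 lists under 0.05. These choices, the 41 gene lists and the rule for named genes were fixed before the data were examined. The niche gene Nov was not matched by symbol. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

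The genes named are Bap1, then in each direction the 10 genes with the largest absolute log2 fold change among those that passed and whose groups did not overlap, leaving out predicted genes and pseudogenes. Up to 4 members with the smallest p of each list and every measured niche factor complete the rule. The report gives most of these genes, a few are not reported here, and any other gene is said to be chosen after its values were seen.

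The alternatives tried were pseudocounts of 0.1 and 0.5, a minimum mean of 0.1 or 5 RPKM or none, and scaling to equal totals, by TMM, by median of ratios or by quantiles. Others were a variance prior without trend or robust to extreme genes, sample weights, the replicate number as a block, an adjusted p under 0.1, an absolute log2 fold change of at least 1, and leaving out each library in turn. Centring each chromosome and centring 20 bins of transcript GC content were added after seeing the data. The procedure was tested on simulated data with 12223 genes, of which 200 were changed, in 20 simulations. It recovered 21.9% of genes changed by 0.5 on the log2 scale, 82.7% at 1 and 97.2% at 2, and 5.66% of its calls were false. All 20 changed lists and 1 of 40 unchanged lists were called. The simulated genes varied independently, with the same spread in both groups taken from the fit itself, and each changed list held raised genes only. The simulation therefore cannot check the preset correlation or the effect of an unequal spread, and it changed far fewer genes than the 61.2% called in the data.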

Results

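Polyadenylated RNA of mouse endosteal mesenchymal stromal cells, the stromal cells that line the inner surface of bone, was sequenced in 6 libraries. The labels place 3 libraries in the Bap1 WT group (Bap1fl/fl) and 3 in the Bap1 cKO group, in which Cre recombinase under the limb mesenchyme promoter Prx1 was combined with the floxed allele. Bap1 encodes the deubiquitinase that removes ubiquitin from histone H2A. Per the series title, the comparison asks how loss of Bap1 changes the transcriptome of the stromal cells that support lymphocyte formation. The RPKM values held 17697, 17705 and 17798 genes above 0 in the WT libraries and 17664, 17782 and 18925 in the cKO libraries. The depths estimated from the steps between low values, in megafragments (M), were 14.5, 13.1 and 14.8 in the WT libraries and 13, 14.3 and 22.1 in the cKO libraries. A single fragment per effective kilobase was then worth 0.0452 to 0.077 RPKM, and 3 fragments were worth 0.136 to 0.231 RPKM, a floor that covers counting error only. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

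Bap1 itself (chromosome 14, 31251450 to 31259944, GRCm38) was not lower in the cKO group. Its RPKM was 22.8, 22.72 and 24.01 in the WT libraries and 28.27, 25.16 and 22.99 in the cKO libraries, a log2 difference of 0.13 ± 0.10 (SE) with a limma Benjamini-Hochberg adjusted p of 0.29. An RPKM summed over the whole gene cannot show whether the floxed exons were removed, since a shortened transcript is counted with the intact one. The value therefore does not check the labels, and the groups are called the libraries labelled Bap1 WT and the libraries labelled Bap1 cKO in what follows.

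The 2 groups lay far apart. Across genes, Pearson's r of log2(RPKM + 1) was 0.987 to 0.988 between WT libraries, 0.948 to 0.974 between cKO libraries and 0.757 to 0.824 between the groups. Genes are not independent replicates, so these r values describe the libraries and carry no test. The first principal component held 86.7% of the variance and separated the groups. Library cKO replicate 3 lay at 53.02 on it, against 79.8 and 80.27 for cKO replicates 1 and 2 and −69.79 to −71.99 for the WT libraries.

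**Figure D1:**
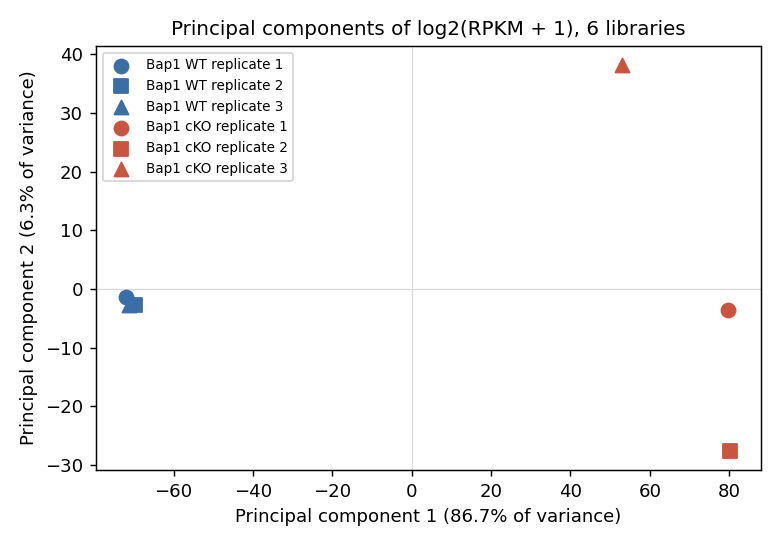
Position of each library on principal components 1 and 2 of log2(RPKM + 1), in arbitrary units, with the WT libraries in blue and the libraries labelled cKO in red. The WT libraries lie together near −70 on component 1, and cKO replicate 3 (53.02) lies nearer to them than cKO replicates 1 (79.8) and 2 (80.27).

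Biglycan (Bgn), a matrix proteoglycan, fell 117-fold from 1780 ± 36.3 to 15.3 ± 18.6 RPKM (mean ± SD, n = 3 libraries per group here and below), and 373-fold without cKO replicate 3. The collagen chains Col1a2 and Col3a1 fell 78.7-fold and 84.4-fold (122-fold for Col1a2 without cKO replicate 2 and 203-fold for Col3a1 without cKO replicate 3), and the fatty acid binding protein Fabp4 fell 150-fold from 401 ± 8.87 to 2.67 ± 1.19 RPKM. Smoc2, a matricellular protein, fell 252-fold. S100g, the calcium-binding protein calbindin-D9k, was listed at 0 in all 3 WT libraries and at 5207.36, 4665.89 and 1604.13 RPKM in the cKO libraries. Cdo1, a cysteine dioxygenase, rose from 0.263 ± 0.179 to 277 ± 33 RPKM, complement C3 rose from 0.147 ± 0.203 to 257 ± 153 RPKM, and the transcription factor Pax8 rose from 0.173 ± 0.0473 to 183 ± 59.6 RPKM.

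Of 12223 genes with a mean of at least 1 RPKM, 4237 were higher and 3239 lower in the libraries labelled cKO (limma, Benjamini-Hochberg adjusted p under 0.05), which is 61.2% of the genes tested. With an absolute log2 fold change of at least 1 as well, 1632 were higher and 1499 lower. The values of the groups did not overlap for 4795 genes in the higher direction and 3637 in the lower, 69% of those tested, where chance gives 10% for 3 against 3. An exact permutation test of 3 against 3 cannot go below 0.1, so the calls rest on limma's pooled estimate of the spread. That estimate is shared by both groups, whose spreads differed. In genes with enough estimated fragments, the median squared difference between WT libraries was 1.84 to 4.93 times counting noise. Between cKO libraries it was 9.54 to 19.67 times. Sample weights were 1.24 to 2.45 for the WT and 0.249 to 0.803 for the cKO libraries, and with them 4459 genes were higher and 3488 lower. Folds are ratios of the group means of RPKM and are left out, in favour of the values, where a library of the lower group lay under its floor of 3 fragments. Every gene called higher or lower and named here had its 3 cKO values beyond its 3 WT values. Without cKO replicate 3, 4483 genes were higher and 3623 lower.

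The other genes with the largest changes on the log2(RPKM + 1) scale included secreted proteins in both directions. Higher in the libraries labelled cKO were Igfbp6, 396-fold to 301 ± 66.7 RPKM (669-fold without WT replicate 1), and Klk1, Pnoc, Tmem213, Mboat2 and Klk1b21, all listed at 0 in every WT library. Klk1 stood at 1626.68, 938.68 and 110.47 RPKM in cKO replicates 1 to 3, Pnoc at 1655.34, 177.46 and 255.51, Tmem213 at 384.39, 237.77 and 58.95, Mboat2 at 216.5, 202.53 and 75.88, and Klk1b21 at 288.52, 414.9 and 24.42. Lower were Car3, from 105 ± 2.57 to 0.01 ± 0.0173 RPKM, Prl2c2, from 647 ± 76.6 to 0.0233 ± 0.0404 RPKM, and Rpl39l, Prl2c3 and Sfrp2, listed at 0 in every cKO library. Rpl39l stood at 277.04, 267.34 and 291.04 RPKM in the WT libraries, Prl2c3 at 157.32, 99.45 and 153.83, and Sfrp2 at 77.07, 55.14 and 72.03. Klk1 with Klk1b21, and Prl2c2 with Prl2c3, belong to families of near-identical copies, so the split of fragments between family members is uncertain.

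Factors that maintain haematopoietic and lymphoid progenitors were mostly lower. Of 17 tested members of the niche list, 11 fell, 4 rose and 2 did not pass, with the same counts adjusted over the list alone. Cxcl12, the chemokine that retains stem cells and B cell progenitors in the marrow, fell 16.1-fold from 508 ± 17.2 to 31.6 ± 28.4 RPKM, and 33.3-fold without cKO replicate 3. Kitl (stem cell factor) fell 12.7-fold to 2.41 ± 0.179, Angpt1 fell 43.6-fold to 0.507 ± 0.142, Vcam1 fell from 13.5 ± 0.514 to 0.387 ± 0.361 RPKM and Csf1 fell 10.2-fold to 42.5 ± 46 RPKM (27.2-fold without cKO replicate 3). The transcription factor Ebf1 fell from 11.4 ± 1.4 to 0.06 ± 0.0624 RPKM, and its paralog Ebf3 fell 2.27-fold. Bmp4 and Ptn fell 2.73-fold and 1.93-fold, Tnfsf11 fell from 2.31 ± 0.195 to 0.117 ± 0.0723 RPKM and Il15 from 2.45 ± 0.6 to 0.213 ± 0.21 RPKM. Foxc1, a transcription factor of niche stromal cells, rose 5-fold from 12.4 ± 1.64 to 62 ± 6.33 RPKM, Jag1 and Flt3l rose 2.71-fold and 1.83-fold, and Thpo rose from 0.103 ± 0.0551 to 1.97 ± 0.921 RPKM. Cdh2 (41.4 ± 2.61 and 60.7 ± 30.9 RPKM) and Igf1 (13.9 ± 2.81 and 41.2 ± 36.2 RPKM) did not pass.

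The niche list was lower as a set (camera Benjamini-Hochberg adjusted p = 0.0181), with an adjusted p = 0.448 with an estimated correlation. Il7, the cytokine required for B cell development, was under the test's minimum, at 1.18, 1.47 and 0.95 RPKM in the WT libraries and 0.55, 0.67 and 1.12 in the cKO libraries. Lepr, a marker of perisinusoidal stromal cells, reached at most 0.14 RPKM in any library. The call of Jag1 was lost without WT replicate 3 (limma adjusted p = 0.0545), that of Flt3l was lost with each chromosome centred (0.78), and Igf1 passed without cKO replicate 2 (0.00312).

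**Figure D2:**
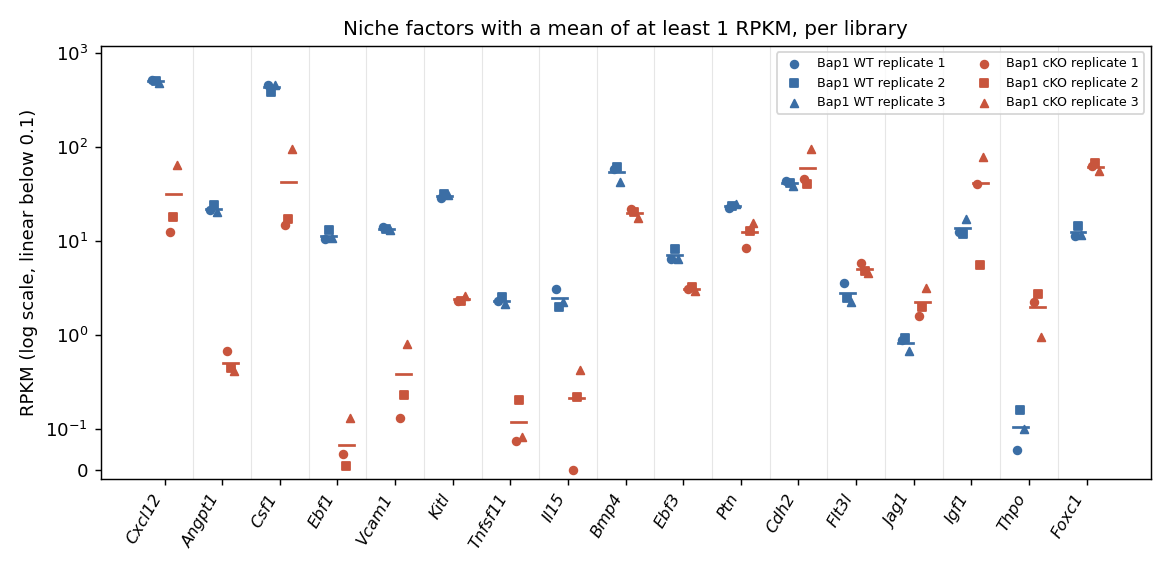
RPKM of the 17 tested niche factors in each library (log scale, linear below 0.1), with WT libraries in blue, libraries labelled cKO in red, a marker shape per replicate and a bar at each group mean, ordered by log2 fold change. Cxcl12 stands at 488.27 to 521.07 RPKM in the WT libraries and at 12.41 to 64.22 in the cKO libraries, while Foxc1 stands at 11.34 to 14.29 and at 55.33 to 67.92.

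Osteoblast genes were mostly lower, and genes of adipocytes, chondrocytes and tendon went both ways. Of 12 tested osteoblast genes 9 fell and none rose. Alpl, the tissue-nonspecific alkaline phosphatase, fell from 22.8 ± 0.622 to 0.153 ± 0.0586 RPKM, Smpd3 fell from 3.33 ± 0.231 to 0.22 ± 0.0624 RPKM and Sparc (osteonectin) fell 3.46-fold from 1640 ± 77.2 to 473 ± 81.9 RPKM. The osteoblast list had a camera Benjamini-Hochberg adjusted p of 0.000845, with an adjusted p = 0.448 with an estimated correlation. Of 11 adipocyte genes 6 fell and 4 rose (7 and 4 adjusted over the list alone, against 9 and 0 for the osteoblast genes). Pparg, the master regulator of adipogenesis, fell from 64.3 ± 3.72 to 0.127 ± 0.0961 RPKM, Lpl from 18.5 ± 2.25 to 0.287 ± 0.0896 and Zfp423 from 4.47 ± 0.415 to 0.397 ± 0.215 RPKM. The adipocyte list had a camera adjusted p of 0.0461 (Benjamini-Hochberg), with an adjusted p = 0.448 with an estimated correlation, and lost its call without cKO replicate 3 (0.116), without cKO replicate 2 (0.0623) and under TMM, median-of-ratios and quantile scaling (0.0767, 0.0806 and 0.0634), among others. Against cKO replicates 1 and 2, cKO replicate 3 stood 0.25 higher on the osteoblast genes, and its median log2 difference on the adipocyte genes was −0.28.

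The chondrocyte genes Col11a1 and Sox9 rose 56.5-fold and 6.66-fold, Cnmd rose from 0 in every WT library to 14.36, 2.92 and 7.39 RPKM, and Sox5 fell from 2.63 ± 0.202 to 0.00667 ± 0.00577 RPKM. In all, 4 of 7 rose and 2 fell, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.786; adjusted p = 0.83 with an estimated correlation). Of 8 tendon and fibroblast genes 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.962 after Benjamini-Hochberg; adjusted p = 0.979 with an estimated correlation). On these genes cKO replicate 3 stood 0.73 above the other cKO replicates (median log2). Scx, a tendon transcription factor, rose 6.84-fold. Decorin (Dcn), a matrix proteoglycan, was listed at 0 in every WT library and at 131.45, 170.63 and 79.25 RPKM in the cKO libraries. Fbln1 fell 7.48-fold from 14.6 ± 0.533 to 1.95 ± 1.19 RPKM, and 11.3-fold without cKO replicate 3.

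Among surface markers of mesenchymal stromal cells, endoglin (Eng) fell 54.5-fold to 0.723 ± 0.206 RPKM and Thy1 fell from 12.5 ± 2.11 RPKM to 0, 0 and 0.22 in cKO replicates 1 to 3, while podoplanin (Pdpn) rose 11.5-fold to 237 ± 56.2 and Cspg4 (NG2) rose from 0.0167 ± 0.0208 to 4.71 ± 1.26 RPKM. In this list 7 of 15 fell and 3 rose, the same adjusted over the list alone, with a camera Benjamini-Hochberg adjusted p of 0.0876, an adjusted p = 0.545 with an estimated correlation, and 0.0462 without cKO replicate 3, which stood 0.35 above the other cKO replicates (median log2).

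The smooth muscle and contractile genes divided the libraries labelled cKO. Across the list cKO replicate 3 stood 3.43 above cKO replicates 1 and 2 (median log2 difference). Acta2, the smooth muscle actin, stood at 2030 ± 102 RPKM in the WT libraries and at 68.78, 149.26 and 1532.34 in cKO replicates 1 to 3. Myl9 stood at 18.89, 39.13 and 303.35 RPKM in the cKO libraries against 346 ± 13.7 in WT, and Tpm2 at 26.89, 34.27 and 259.82 against 286 ± 20.2. In these genes cKO replicate 3 stayed below the WT libraries. In Tagln and Actg2, chosen after their values were seen, it stood above them. Tagln was at 1006.19 RPKM against 152.25 to 203.47 in WT, and Actg2 at 33.22 against 8.73 to 9.29. Of 8 tested members 2 fell, Acta2 and Lmod1, and none passed adjusted over the list alone. The list had a camera Benjamini-Hochberg adjusted p of 0.106 with all libraries and 0.000601 without cKO replicate 3, and an adjusted p = 0.723 with an estimated correlation. The calls of Acta2 and Lmod1 were lost without WT replicate 1, 2 or 3 (limma adjusted p = 0.108, 0.104 and 0.1 for Acta2, and 0.0961, 0.0709 and 0.0847 for Lmod1) and without cKO replicate 1 or 2 (0.11 and 0.113, and 0.0983 and 0.09).

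**Figure D3:**
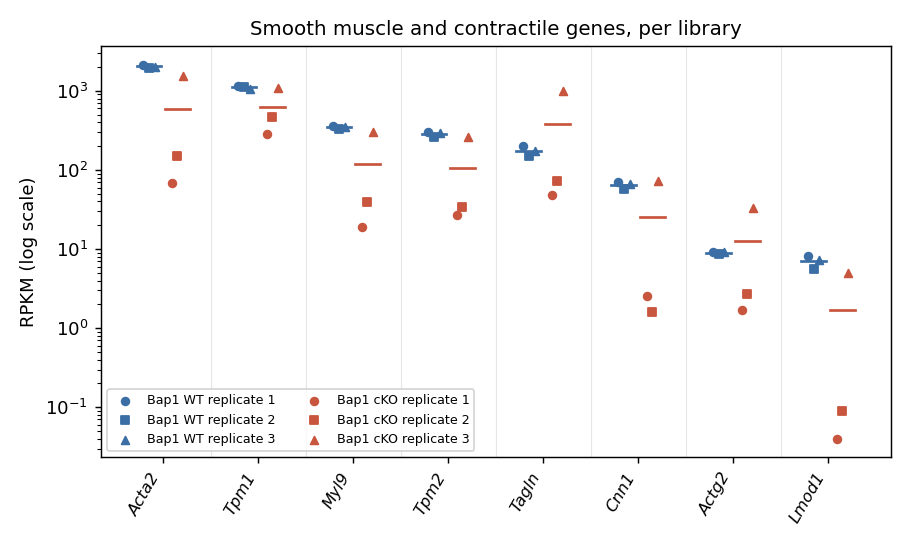
RPKM (log scale) of 8 smooth muscle and contractile genes in each library, with WT libraries in blue, libraries labelled cKO in red, a marker shape per replicate and a bar at each group mean. In cKO replicate 3 Acta2 stands at 1532.34 RPKM, against 68.78 and 149.26 in cKO replicates 1 and 2.

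Collagens and matrix genes fell in large numbers. Of 24 tested members of the matrix list, 15 fell and 6 rose (16 and 7 adjusted over the list alone). Against cKO replicates 1 and 2, cKO replicate 3 stood 0.80 higher on the matrix list and 0.60 higher on the protease list (median log2). Col6a1, Col6a2 and Col6a3, the chains of collagen VI, fell 8.05-fold, 11.3-fold and 69-fold, and periostin (Postn) fell 26.7-fold from 227 ± 12.9 to 8.49 ± 3.97 RPKM. The list had a camera Benjamini-Hochberg adjusted p of 0.0181 and an adjusted p = 0.448 with an estimated correlation. Of 14 matrix proteases and inhibitors 10 fell and 3 rose, as they did adjusted over the list alone (camera adjusted p = 0.0181 after Benjamini-Hochberg; adjusted p = 0.448 with an estimated correlation). The matrix proteases and inhibitors missed the threshold with a minimum mean of 5 RPKM (0.0504). The membrane-type metalloprotease Mmp14 fell 4.36-fold from 231 ± 5.59 to 52.9 ± 14 RPKM, Mmp23 fell 73.7-fold, Mmp19 fell 6.94-fold and the collagenase Mmp13 fell from 4.14 ± 0.575 to 0.0333 ± 0.0351 RPKM.

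Wnt pathway genes fell in 10 of 16 cases and rose in 5, also when adjusted over the list alone. The ligand Wnt10b, which promotes bone formation, fell from 39.7 ± 3 to 0.157 ± 0.0643 RPKM, and the secreted inhibitor Sfrp1 fell from 15.6 ± 0.725 to 0.12 ± 0.0819 RPKM, while Dkk3 rose 8.68-fold to 496 ± 59 RPKM. The list had a camera Benjamini-Hochberg adjusted p of 0.0321 and an adjusted p = 0.448 with an estimated correlation, with 0.128 without cKO replicate 3. The call of the Wnt pathway genes was also lost under TMM, median-of-ratios and quantile scaling (0.0764, 0.0806 and 0.0543), among others. Of 18 BMP and TGF-beta pathway genes 9 rose and 1 fell (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.484 (Benjamini-Hochberg) and an adjusted p = 0.723 with an estimated correlation. The member that fell was Inhba, the activin A subunit, from 128 ± 22.2 RPKM to 0.2, 0.4 and 4.62 in cKO replicates 1 to 3. On these genes cKO replicate 3 stood 0.36 above the other cKO replicates (median log2). Bmp3 was listed at 0 in every WT library and at 75.6, 57.08 and 17.39 RPKM in the cKO libraries. Chrd rose from 0.203 ± 0.118 to 4.32 ± 1.34 RPKM, and Tgfb1 rose 1.68-fold, a call that was lost with each chromosome centred (limma adjusted p = 0.582).

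Hedgehog and Notch genes rose in 4 and fell in 4 of 10 cases, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.981; adjusted p = 0.981 with an estimated correlation). Hes1, a Notch target, rose 10.5-fold, Hhip rose from 0.177 ± 0.172 to 10.3 ± 6.18 RPKM, and Smo and Gli3 fell 1.47-fold and 2.55-fold. In the IGF axis 4 of 11 genes rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.694 after Benjamini-Hochberg; adjusted p = 0.814 with an estimated correlation). On these genes cKO replicate 3 stood 0.27 above the other cKO replicates (median log2). The imprinted RNA H19 rose from 0.583 ± 0.362 to 80.2 ± 27.1 RPKM, Igfbp5 fell 4.69-fold and Igf2bp1 fell from 4.19 ± 0.459 RPKM to 0.03, 0.04 and 0.37 in cKO replicates 1 to 3.

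Genes of a list built around PR-DUB, the complex in which Bap1 acts, were mostly higher. Of 12 tested members 9 rose, none fell and 3 did not pass, the same adjusted over the list alone. Foxk2 rose 2.24-fold from 17.9 ± 1.3 to 40 ± 4.87 RPKM, Asxl2 rose 2.13-fold, Ogt, the O-GlcNAc transferase, rose 1.97-fold and Brca1 rose 2.14-fold. Foxk2 and Brca1 (log2 differences of 1.11 and 0.96) lie on chromosome 11, whose genes had a median of 0.44 (0.81 in its distal part). Asxl2 (1) lies on chromosome 12, with a median of 0.62, and Ogt (0.96) on the X chromosome, with −0.17. Part of the rise of Foxk2, Brca1 and Asxl2 was thus shared with their chromosomes. The list had a camera Benjamini-Hochberg adjusted p of 0.0181 and an adjusted p = 0.448 with an estimated correlation. The opposing Polycomb complexes went both ways, with 10 of 29 genes higher and 7 lower, the same adjusted over the list alone (camera adjusted p = 0.786 after Benjamini-Hochberg; adjusted p = 0.876 with an estimated correlation). Ezh1, a histone H3 methyltransferase, rose 4.03-fold and Phf19 rose from 0.413 ± 0.255 to 5.63 ± 0.612 RPKM, while Cbx6 fell 6.89-fold and Bmi1 fell 2.42-fold.

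Hox genes, which set position along the body axis, changed in both directions. Hoxb2 to Hoxb9, chosen as a block after their values were seen, are 8 genes on chromosome 11 between 96271457 and 96354012 (GRCm38) that stood at 1.55 to 9.94 RPKM in the WT libraries and were listed at 0 in all 3 cKO libraries. Hoxb3, for instance, stood at 6.58, 8.39 and 7.52 RPKM, Hoxb6 at 9.1, 9.39 and 9.94, and Hoxb9 at 9.67, 8.97 and 8.64 RPKM in the WT libraries. Hoxc13 fell from 29.9 ± 1.65 to 0.123 ± 0.15 RPKM. Of 22 tested Hox genes 12 fell and 5 rose, the same adjusted over the list alone, and those that rose, named after their values were seen, were Hoxa7, Hoxa9, Hoxc6, Hoxc8 and Hoxc9. The list had a camera Benjamini-Hochberg adjusted p of 0.0181 and an adjusted p = 0.448 with an estimated correlation. It lost its call with a minimum mean of 5 RPKM (0.921), which removes the 8 Hoxb genes, and with each chromosome centred (0.108).

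**Figure D4:**
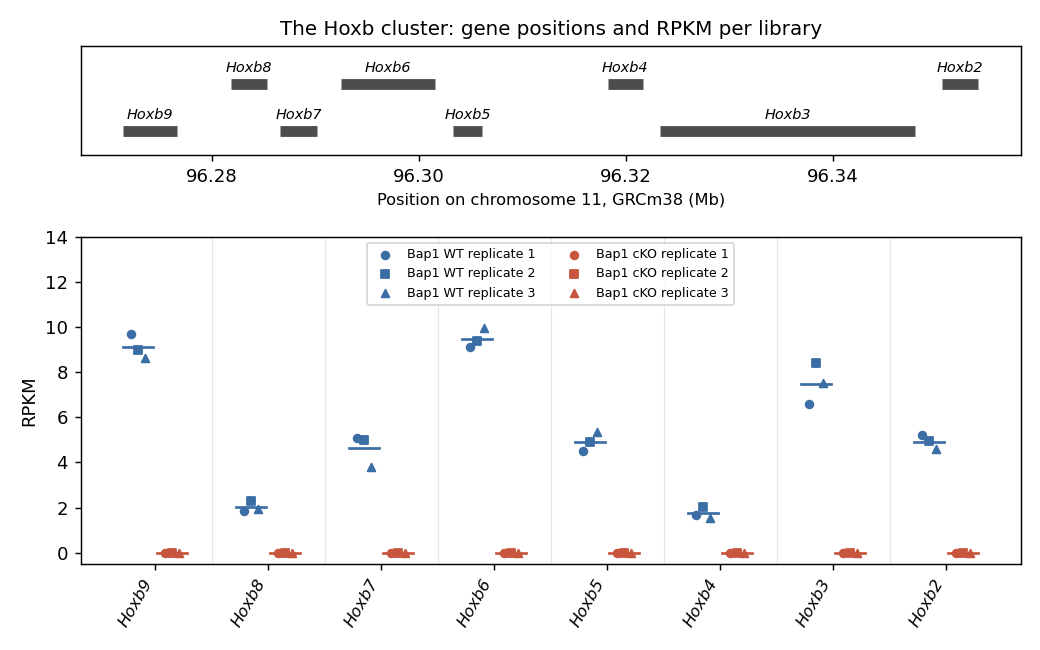
Positions of 8 Hoxb genes on chromosome 11 of GRCm38 (Mb, above) and their RPKM per library (below), with WT libraries in blue, libraries labelled cKO in red, a marker shape per replicate and a bar at each group mean. The WT libraries stand at 1.55 to 9.94 RPKM and each cKO library is listed at 0.

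Of 16 tested limb and developmental transcription factors 7 fell and 6 rose, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.621; adjusted p = 0.723 with an estimated correlation). Msx2 fell 16.7-fold. Osr1 rose 9.82-fold, and Six2 was listed at 0 in every WT library and at 13.36, 13.84 and 12.52 RPKM in the cKO libraries.

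Antigen presentation genes were lower in 7 of 9 cases and higher in 1, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0181; adjusted p = 0.448 with an estimated correlation). The antigen presentation genes missed the threshold with a minimum mean of 5 RPKM (0.0504). The peptide transporter genes Tap1 and Tap2 fell 5.3-fold and 6.46-fold, the immunoproteasome subunit Psmb8 fell from 9.08 ± 1.16 to 0.307 ± 0.122 RPKM, and the class I gene H2-K1 rose 3.45-fold. Interferon-stimulated genes fell in 5 and rose in 2 of 9 cases, the same adjusted over the list alone (camera adjusted p = 0.192 after Benjamini-Hochberg; adjusted p = 0.448 with an estimated correlation). Ifih1 fell from 3.35 ± 0.266 to 0.317 ± 0.118 RPKM, Ifit2 fell 8.66-fold, Xaf1 fell 2.96-fold, and Isg15 was listed at 0 in every cKO library and at 2.27, 2.68 and 3.02 RPKM in WT. Of 10 inflammatory genes 5 fell and 3 rose, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.444; adjusted p = 0.723 with an estimated correlation). The inflammatory genes stood 0.88 higher in cKO replicate 3 than in the other cKO replicates (median log2). The chemokine Cxcl1 fell 22.1-fold and Ccl9 fell from 52.8 ± 5.62 RPKM to 0.1, 0.77 and 0.17 in cKO replicates 1 to 3, while Nfkbia, the inhibitor of NF-kappa-B, rose 20.8-fold to 372 ± 31.1 RPKM and Csf3 rose from 0.0567 ± 0.0603 to 43.2 ± 18.6 RPKM.

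Cell cycle genes fell in 15 and rose in 4 of 26 cases, the same adjusted over the list alone. Their camera Benjamini-Hochberg adjusted p was 0.025, and 0.723 with an estimated correlation. The rotation test fry did not call them either (adjusted p = 0.0829). This was the only list called by camera at the preset correlation that fry did not call. The others had a fry adjusted p from 4e-05 (Hox and Wnt lists) to 0.00445 (p53 list), in camera's direction. Aurka fell 2.7-fold, Ccne1 2.28-fold, Ccnb1 2.06-fold and E2f1 1.73-fold. Of 16 p53 targets and cell cycle inhibitors 10 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.0181 after Benjamini-Hochberg; adjusted p = 0.545 with an estimated correlation). In cKO replicate 3 the cell cycle genes stood 0.26 and the p53 list 0.27 above the other cKO replicates (median log2). Mdm2, Ccng1, Sesn2 and Cdkn2b fell 2.55-fold, 4.24-fold, 5.11-fold and 3-fold. The glycolysis and hypoxia genes fell in 12 and rose in 5 of 20 cases, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0321; adjusted p = 0.448 with an estimated correlation; 0.0512 without cKO replicate 3). Eno1 fell 2.08-fold from 541 ± 12.6 to 260 ± 48.9 RPKM, Pgam1 fell 1.7-fold, Pdk1 fell 7.55-fold and Hk2 rose 3.5-fold.

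Sterol synthesis genes fell in 11 and rose in 3 of 18 cases, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0203; adjusted p = 0.448 with an estimated correlation; 0.0826 without cKO replicate 3). Sqle fell 1.8-fold and Mvk 1.71-fold, and Insig1 rose 1.59-fold. Oxidative phosphorylation genes fell in 8 and rose in 5 of 26 cases (7 and 3 adjusted over the list alone), with Ndufa4 1.84-fold lower and Uqcrc2 and Cox7a2 1.84-fold and 1.8-fold higher (camera adjusted p = 0.402 after Benjamini-Hochberg; adjusted p = 0.811 with an estimated correlation). Of 17 unfolded protein response genes 7 fell and 5 rose (9 and 5 adjusted over the list alone), with Calr 1.5-fold lower and Dnajb9 2.63-fold higher (camera Benjamini-Hochberg adjusted p = 0.398; adjusted p = 0.814 with an estimated correlation). The response genes stood 0.28 higher in cKO replicate 3 than in the other cKO replicates (median log2).

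Of the lists that can follow the handling of cells or RNA, the immediate early list passed with all libraries. Of 19 immediate early and dissociation stress genes 11 rose and 1 fell, the same adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0188; adjusted p = 0.448 with an estimated correlation). Fos rose 15.6-fold from 3.13 ± 1.18 to 48.8 ± 19.4 RPKM, Egr1 rose 9.06-fold, Klf4 18.2-fold and Nr4a1 3.45-fold. Of 26 ribosomal protein genes 14 rose and 5 fell, the same adjusted over the list alone, with Rps6 2.52-fold and Rpl27 1.99-fold higher (camera adjusted p = 0.0784 after Benjamini-Hochberg; adjusted p = 0.723 with an estimated correlation; 0.0451 without cKO replicate 3). Of 13 mitochondrially encoded genes 4 fell and none rose, the same adjusted over the list alone, with mt-Nd1 1.3-fold and mt-Nd2 1.55-fold lower (camera adjusted p = 0.0692 after Benjamini-Hochberg; adjusted p = 0.723 with an estimated correlation). The call of mt-Nd1 was lost under quantile normalization (limma adjusted p = 0.291). The list of mitochondrially encoded genes passed without WT replicate 1 (0.042), WT replicate 3 (0.0346) or cKO replicate 3 (0.0451). Of 8 replication-dependent histone genes 1 rose and none fell, the same adjusted over the list alone. It was Hist1h2bj, at 0.78 ± 0.329 and 2.31 ± 0.346 RPKM (camera Benjamini-Hochberg adjusted p = 0.866; adjusted p = 0.974 with an estimated correlation). Between cKO replicate 3 and the other cKO replicates the median log2 difference was −0.34 for the immediate early, −0.11 for the ribosomal and −0.70 for the histone genes.

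In some lists the summaries differed in sign. Tendon and fibroblast genes had a median log2 difference of −0.25 and a mean of 0.45, with camera pointing lower and the rotation test fry higher. The Polycomb list had a median of −0.07 and a mean of 0.07, with both tests pointing lower. Hedgehog and Notch genes had a median of 0.08 and a mean of 0.59, with camera pointing lower and fry higher. The limb factors (median −0.38, mean −0.09) and the inflammatory genes (median −1.65, mean −0.75) pointed lower in camera and higher in fry. The chondrocyte genes (median 1.88, mean 1.19) pointed higher in camera and lower in fry. Of these lists fry called only the tendon and fibroblast genes (adjusted p = 0.00445) and the limb factors (0.00149), and camera called none.

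**Figure D5:**
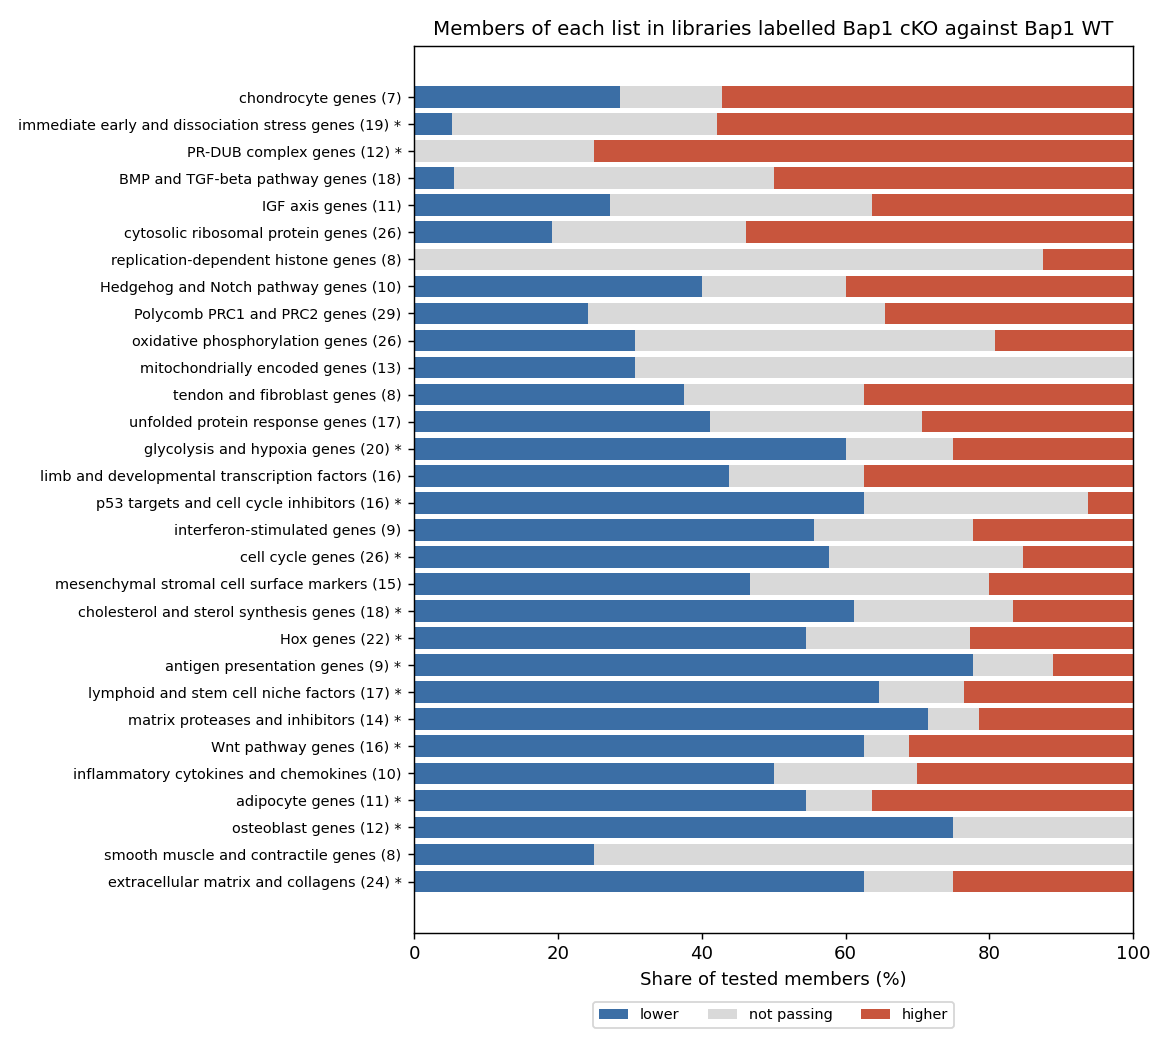
Share (%) of the tested members of each of 30 lists that were lower (blue), did not pass (grey) or were higher (red) in the libraries labelled cKO, with the number of tested members in brackets and an asterisk at a camera adjusted p under 0.05 with the preset correlation. Osteoblast genes show 9 of 12 lower and PR-DUB genes 9 of 12 higher.

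Most markers of other cell types lay under the minimum for testing, and lists with fewer than 5 tested members were given no set test. Of the osteocyte genes 3 were tested (1 rose, 1 fell), of the osteoclast genes 3 (2 fell), of the skeletal muscle genes 3 (1 rose), of the macrophage and monocyte genes 2 (1 rose, 1 fell) and of the glial and neural genes 2 (1 fell). A single tested gene rose for the endothelial (Egfl7), B cell (Blnk) and megakaryocyte and mast cell (Itga2b) lists, the last call being lost without WT replicate 2 (limma adjusted p = 0.066), without WT replicate 3 (0.0521) and with each chromosome centred (0.189), and a single one fell for the neutrophil list (Camp). No gene of the T and NK cell or erythroid lists reached a mean of 1 RPKM, and each of these counts was the same adjusted over the list alone. Cathepsin K (Ctsk) fell 11.4-fold from 34.5 ± 1.6 to 3.02 ± 3.03 RPKM (24.7-fold without cKO replicate 3), Cd14 fell 5.82-fold to 2.05 ± 0.501 and Ackr3 rose 22.9-fold to 21.9 ± 4.14 RPKM. Among members chosen after their values were seen, Hbb-bs reached 2.24 RPKM in cKO replicate 2, Lyz2 reached at most 0.65 and S100a8 at most 0.51, and Tyrobp and C1qa were listed at 0 in all 6 libraries.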

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

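The alternatives that centre each chromosome or the GC bins, and their values, were chosen only after the results were seen, and the others were planned. Leaving out each library in turn gave 3504 to 4483 genes higher and 2626 to 3623 lower in the libraries labelled cKO, 2 to 3 lists higher, 11 to 13 lists lower and a Bap1 difference of 0.05 to 0.20 on the log2 scale. The other alternatives gave a Bap1 difference of 0.01 to 0.17. An absolute log2 fold change of at least 1 left 1632 genes higher and 1499 lower, fewer by its construction. With an estimated correlation 0 lists were higher and 0 lower, since it allows for the correlation that members share. With a minimum mean of 5 RPKM 7 lists were lower, with fewer genes tested. The Hox genes turned there to a signed −log10 p of 0.09 (camera adjusted p = 0.921), as this minimum removed all 8 expressed Hoxb genes from the list. With each chromosome centred Ncam1 turned from a log2 difference of 0.06 to −0.29 (limma adjusted p = 0.0451), by subtracting its chromosome's median.

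The replicate numbers did not pair the libraries, with residual correlations of −0.017, 0.05 and −0.019 between libraries of the same number. With the replicate block 3811 genes were higher and 2938 lower, 2 lists were higher and 11 lower, and Bap1 differed by 0.13 (limma adjusted p = 0.396). The adipocyte genes lost their call there (0.0515). Centring each chromosome gave 3353 genes higher and 3579 lower with 5784 calls shared in direction, and centring the GC bins 3798 and 3841 with 7025 shared. TMM and median-of-ratios scaling gave 49.8% and 49% of changed genes higher, against 56.7% as reported. Of 166 named genes 147 kept direction and side of the threshold throughout, and 10 of 154 that passed lost the call in some alternative. Acta2 also missed the threshold with a minimum mean of 0.1 RPKM (0.0504), without a filter (0.0832), without trend (0.051) and with each chromosome centred (0.0602). Of 30 lists 11 were the same throughout, and all 14 that passed lost the call with an estimated correlation. The cause of these changes was not tested. A count test, planned only for the case that whole counts were present, was not run. The values are RPKM, and the recovered steps depend on a gene length that is not given. Depth limits values under the floor of 0.136 to 0.231 RPKM.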

Other observations

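The tests of depth, blood cells, positional origin, other splits, admixture, random placement and copy number were chosen only after the results were seen, and the GC test was written down before its result. The genes in this part were chosen after their values were seen. Xist, the RNA that silences an X chromosome, fell from 96.8 ± 4.67 RPKM (SD, n = 3) to 5.44, 0.01 and 8.04 in cKO replicates 1 to 3, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were listed at 0 in all 6 libraries. Of the imprinted genes looked at, which were not a list fixed beforehand and were given no set test, Dio3 rose 277-fold and Grb10 10.4-fold, Snrpn rose from 0.197 ± 0.0115 to 18.1 ± 1.98 RPKM and Airn from 0.35 ± 0.274 to 7.05 ± 1.5 RPKM. Peg10 fell from 6.38 ± 0.329 to 0.0433 ± 0.0416 RPKM and Sgce from 38.5 ± 2.77 to 0.507 ± 0.355 RPKM. Meg3 was listed at 0 in every WT library and at 14.29, 1.17 and 35.35 RPKM in the cKO libraries. Igf2 stood at 1.49, 0.98 and 1.17 RPKM in the WT libraries and at 3.59, 15.5 and 1.77 in the cKO libraries and did not pass (limma Benjamini-Hochberg adjusted p = 0.0826). Nor did Ndn (0.0593), Igf2r (0.264) and Impact (0.472), with log2 differences of 1.66, 0.19 and −0.09.

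Pgr, the progesterone receptor, rose 405-fold to 143 ± 60.2 RPKM, Cyp27b1, the enzyme that activates vitamin D, rose from 0.127 ± 0.0702 to 79.7 ± 55.8 RPKM, and the proton pump subunit Atp6v0a4 rose 132-fold to 339 ± 175 RPKM. Vimentin (Vim) fell 6.7-fold from 5780 ± 175 to 862 ± 388 RPKM. Neighbouring genes near 0 in every cKO library formed runs of 8 (Hoxb9 to Hoxb2), 5 (Serpinb9c to Serpinb9g) and 5 (Mcpt8 to Gzmb), where the longest run in 1000 shuffles was 3. A run of 10 genes, Klk1b8 to Klk1, was near 0 in every WT library, where the longest in 1000 shuffles was 4. The shuffles moved genes independently, while these runs are families of related neighbours. They therefore do not show how long a run such families give by themselves. In the Klk1 family the split of fragments between near-identical copies is also uncertain.

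Most expressed genes differed between the groups although Bap1 was not lower. Depth as the whole cause is argued against, since without the deepest library, cKO replicate 3, limma called 8106 genes. Blood or endothelial cells in one group were checked with 16 of their abundant transcripts, a panel chosen after the values were seen. Of these 6 were 0 in every library, and the highest, Hbb-bs, reached 2.24 RPKM in cKO replicate 2. That was above a first bound of 1 RPKM but under 38.5 RPKM. The latter is 1% of the level of the 10 most abundant genes that differed. These values argue against cells that carry the panel transcripts as the whole cause. Outside the panel, the B cell gene Blnk was at 0 in every WT library and at 41.73, 51.15 and 17.33 RPKM in the cKO libraries. Egfl7 of the endothelial list also rose, while Cd14 fell, so the panel cannot exclude such cells. Cultures of a different positional origin may also be involved. All 8 Hoxb genes at 1 RPKM or more in every WT library were listed at 0 in every cKO library. Of the 22 tested Hox genes, however, 12 fell and 5 rose, the latter from the Hoxa and Hoxc clusters. Origin and genotype cannot be told apart because each group holds a single genotype. Of the 10 splits of the libraries, 1 gave as many genes, the real one with 7476. The highest other gave 0 by limma (22 to 129 at an unadjusted p under 0.05). Every other split mixes both labels in each group, which puts the difference between the labels into the spread. Few calls were then bound to follow, so this contrast decides nothing. Besides, 10 splits are too few for a share under 0.05, and genotype stays open and untested.

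Library cKO replicate 3 lay between the groups on the first principal component. If cells like those of the WT libraries were mixed in, the 8 contractile genes would need a median share of 93.9% (70.4 to 820%), while 56 genes found in the WT libraries and nearly absent from cKO replicates 1 and 2 showed a median share of 0.26% and a 95th percentile of 3.64%. The highest share, that of Tagln, is more than a mixture can hold. This argues against admixture as the cause of the contractile levels. A difference in state between cultures stays open, and no biological explanation was tested, since the design gives none within a group.

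Genes on some chromosomes shifted together, with median log2 differences of 0.65 on chromosome 7 and 0.62 on chromosome 12, against 0.09 over 9246 genes, while chromosomes 4, 11 and 16 were shifted over a part (1.05 and −0.08, 0.18 and 0.81, and −0.08 and −0.56 in the proximal and distal parts) and chromosomes 9, 6, 18 and 19 more evenly and by less (0.36 and 0.42, −0.25 and −0.26, −0.21 and −0.25, and −0.18 and −0.26). Random placement of single genes is argued against by a permutation p of 0.0005, the smallest that 2000 shuffles can give. The shuffles moved genes independently, so they do not show how far neighbours that change together widen the chromosome medians. Transcript GC content is argued against by a chromosome 7 median of 0.63 with GC bins centred. A copy number difference is a candidate explanation, as a hypothesis: the proximal and the distal parts of chromosomes 7 and 12 were each shifted by at least 0.48 relative to all genes, where a gain from 2 to 3 copies gives 0.58, but it was tested on these chromosomes only. Chromosomes 7 and 12 had the highest medians of all, so a shift in both of their parts was likely beforehand and decides little. Chromosome 4, shifted over a part, was not put to this test. Chromosome 8 differed by 0.31 between cKO replicates 2 and 1, while no WT contrast exceeded 0.05 on any chromosome. RNA levels alone do not show DNA copies, and genotype stays open and untested.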
